A study of Homo sapiens with 18 samples.

How the data were processed

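RNA from PC3 cells, an established human prostate cancer line, was sequenced in 18 libraries from 6 groups of 3. In the knockdown experiment the cells carried a lentiviral short hairpin RNA against Elongin B (EloB KD) or Elongin C (EloC KD), or a control hairpin (Control KD), and grew in medium with 10% serum. In the peptide experiment they were treated for 24 h with 12.5 µM of a wild-type BC-box peptide (WT peptide), a mutant BC-box peptide or a scrambled peptide, in 2.5% serum. Total RNA was purified on columns with DNase digestion and made into stranded mRNA libraries, per the labels' protocols. The labels give replicate numbers 1 to 3 and do not say whether replicates were separate cultures, so p-values measure the spread between these samples.

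The reads were aligned to hg38, counted per gene with featureCounts and compared with DESeq2, per the submitters' processing notes, which give no versions. The authors deposited the signal of each library as a DESeq2-normalised read count, in 1 table for each experiment with 20365 genes, of which 596 carry an Ensembl identifier only. Dividing by each library's smallest step gave back whole reads within a tolerance of 0.05 reads. No read was counted in any library for 2467 genes of the knockdown table and 3045 of the peptide table. The authors also deposited DESeq2 results of 4 comparisons, with a log2 fold change, a test statistic (a score) and an adjusted p-value for each gene. These deposited tables have no header, and their columns were identified from their values. Other cells of these deposited tables hold spreadsheet error text in place of a value for genes without a read. In both deposited comparisons with Control KD the sign of the fold change is opposite to that of the statistic for 17601 genes (EloB KD) and 17566 genes (EloC KD); the fold change has the direction of the normalised counts. The deposited results called 3420 genes for EloB KD, 6269 for EloC KD, 6801 between the knockdowns and 506 for the WT peptide. They were set beside the calls made here and entered no test. The authors' results for the mutant peptide were not analysed here.

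For the main test, limma (version 3.58.1, in R 4.3.3) was fitted with an intensity trend to log2 of the normalised count plus 1, for genes with a mean of at least 10 over the 9 libraries of an experiment. This left 13764 genes in the knockdown experiment and 13105 in the peptide experiment. The 3 groups of an experiment shared 1 estimate of the spread, and 6 comparisons were made, each 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Errors of log2 fold changes are standard errors of this fit and errors of levels are SDs, with n = 3 throughout. A pair of groups of 3 cannot give an exact permutation p below 0.1, so single genes rest on the model fitted across all genes. The same comparisons were run with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads.

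A set of 37 gene lists was fixed from textbook knowledge before the data were examined, as were the design, the alternatives and the rule for genes named in the text. Lists with at least 5 measured members were tested with camera in limma against all other genes with a preset correlation of 0.01, adjusted over the 36 lists tested per knockdown comparison or the 35 per peptide comparison. Each test was repeated with an estimated correlation, and with fry. Member counts are given from the adjustment over all genes and adjusted over the list alone. A list score is the mean log2 level of a list's members in a library, less the mean over the control libraries.

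Genes named in the text are ELOB, ELOC and ELOA in every comparison. They include, per comparison with a control, genes among the 10 highest and 10 lowest log2 fold changes, and 5 and 5 for EloB KD against EloC KD and for the WT against the mutant peptide. These had to have an adjusted p under 0.05, a mean of at least 50 over the 6 libraries compared, groups that do not overlap, and a gene symbol. For each list the 4 members with the smallest adjusted p could be named, and for genes called in both knockdowns and with the WT peptide the 10 largest in the same and in opposite directions. Genes outside this rule are said to have been chosen after their values were seen. Gene positions are from the GENCODE annotation of GRCh38, which was matched to 20219 of the 20365 genes for annotated length.

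Pairing by replicate number was checked by correlating deviations from the group means across genes. Same-number libraries gave 0.236 to 0.566 in the knockdown and 0.254 to 0.715 in the peptide experiment. Other pairs gave -0.439 to 0.0703 and -0.546 to 0.336. The knockdown samples pair clearly, and of the peptide samples only replicate 2 (0.697 to 0.715). The main fit leaves pairing out, and a block by replicate number was an alternative throughout. Other alternatives were TMM and quantile scaling, other pseudocounts and filters, stricter thresholds, a fit of only the 6 libraries compared, and leaving out each library in turn. After the data were seen, edgeR with the block and fits without replicate 2 of every peptide group were added. So was removing each library's trend with annotated length, with the block.

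The fits were tested on simulated data with 50 genes changed at each size, 200 in all. The data were drawn on the real means and library sizes of each comparison. At a log2 change of 1, limma recovered 33 of 50 genes for EloB KD, 39 for EloC KD, 41 for the WT peptide, 45 for the mutant peptide and 43 between the peptides. At a log2 change of 0.25 it recovered 1, 0, 2, 3 and 3 of 50. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.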

Results

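Gene expression was measured by RNA sequencing in PC3 cells in which an Elongin subunit was depleted by a short hairpin RNA, or which were exposed to a peptide carrying a BC-box. Elongin B and Elongin C form a heterodimer that binds Elongin A, a transcription elongation factor, and that also serves as the adaptor of cullin ubiquitin ligases, whose substrate receptors (among them VHL) bind it through a BC-box. The knockdown experiment had 3 libraries each of EloB KD, EloC KD and Control KD, with 40.3 to 57.2 M reads counted per library. The peptide experiment had 3 libraries each of the WT, mutant and scrambled peptide, with 31.7 to 34.7 M reads. Between 13429 and 14026 genes in the knockdown libraries and 13054 to 13252 in the peptide libraries had at least 10 reads. The share of reads from mitochondrial genes was 2.60% to 4.75% in the knockdown libraries and 3.32% to 4.82% in the peptide libraries. Sampling of reads was a small part of the spread, since the chi-square per degree of freedom between replicates was 5.06 to 78.4.

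The largest component of variation separated EloC KD from the other libraries in the knockdown experiment (51.2% of the variance). In the peptide experiment it separated replicate 2 of every group from replicates 1 and 3 (44.0%).

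The EloB KD libraries were compared with Control KD to ask what depletion of Elongin B does to the transcriptome. The targeted gene ELOB (chromosome 16, 2771414 to 2777297, GRCh38) had normalised counts of 596.3, 478.3 and 535 in the EloB KD libraries and of 2626, 4118 and 4950 in Control KD. ELOB fell by 2.82 ± 0.20 on the log2 scale, 7.04-fold, with an adjusted p of 3.55e-05 in limma. ELOC, which encodes the partner subunit (chromosome 8, 73939169 to 73972287), had a log2 fold change of 0.01 (adjusted p 0.971; 4502 ± 361 against 4480 ± 355 normalised counts). ELOA, which encodes the elongation factor subunit (chromosome 1, 23743155 to 23762059), had a log2 fold change of -0.23 (adjusted p 0.149).

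**Figure D1:**
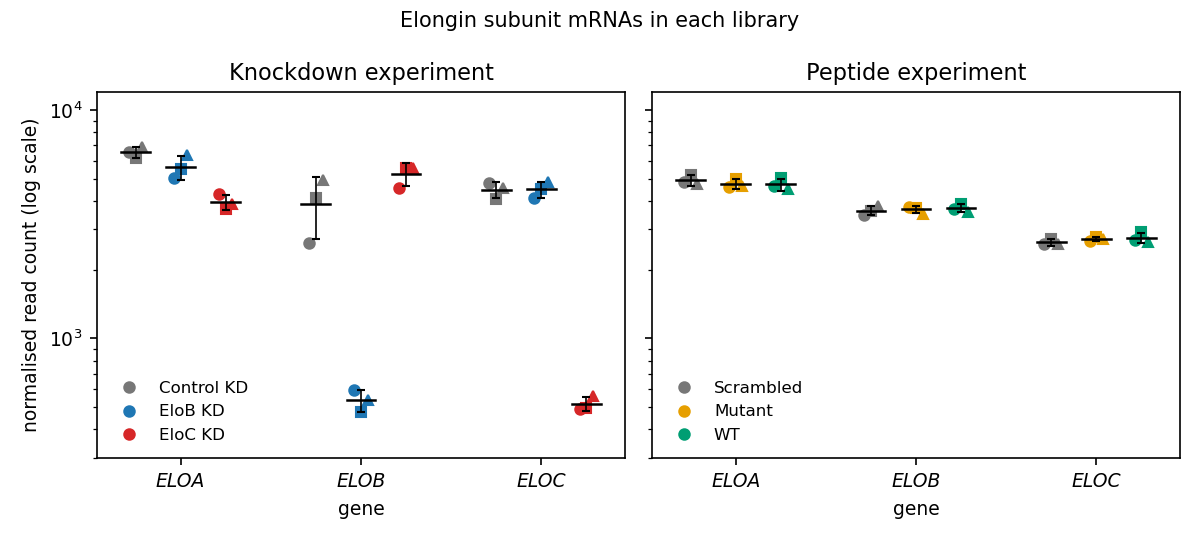
Normalised read counts of ELOB, ELOC and ELOA in every library of both experiments, with the group mean as a line and the SD as a bar. ELOB lies between 478.3 and 596.3 in EloB KD and ELOC between 491.8 and 557.9 in EloC KD, while the peptide groups overlap for each of these genes.

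ARNT2, a bHLH-PAS transcription factor that dimerises with HIF-1α and SIM1, rose 27.9-fold in EloB KD (621.6 ± 133 against 21.24 ± 4.49 normalised counts; log2 4.8 ± 0.28, adjusted p 1.27e-05; chromosome 15, 80404350 to 80597937). The muscle nicotinic receptor subunit CHRNA1 rose 13.3-fold, the ephrin receptor EPHB1 11.9-fold and the myogenic transcription factor MYOD1 7.49-fold. HLF, a PAR bZIP transcription factor, fell 11.5-fold (92.91 ± 28 against 1094 ± 398; adjusted p 0.000199). The secretory pathway pseudokinase FAM20A fell 9.48-fold and FST, the secreted antagonist of activin, 4.57-fold. In all, limma called 2822 of 13764 genes, 1285 higher and 1537 lower, and 680 of them changed at least 2-fold. With the replicate number as a block 4996 genes were called, among them all 2822. DESeq2 called 3447 and edgeR 2878 genes, and 2791 of the 2822 were also called in the authors' table, none in the opposite direction.

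Genes of cholesterol and fatty acid synthesis fell in EloB KD: 13 of 28 measured members were lower and 1 higher (15 and 1 adjusted over the list alone), with a median log2 fold change of -0.35. FADS1 (log2 -1.28 ± 0.17) and FADS2 (-0.90 ± 0.12) encode fatty acid desaturases, and INSIG1 (-1.25 ± 0.21) an endoplasmic reticulum protein that retains SREBP. The camera test gave an adjusted p of 0.000251 for this list, and an adjusted p = 0.979 with an estimated correlation. HOX genes rose as a list, with 12 of 29 members higher and 3 lower (15 and 3 adjusted over the list alone, 18 and 3 with the block) and a median of 0.64. The test gave an adjusted p of 0.00123, and adjusted p = 0.979 with an estimated correlation. HOXC6 (log2 0.95 ± 0.18) and HOXB4 (1.52 ± 0.32) were higher, whereas HOXB13, the prostate lineage factor, was lower (-1.17 ± 0.18). Ribosomal protein genes were lower by a small amount as a list, with 6 of 62 lower and none higher (5 lower adjusted over the list alone, 16 with the block) and a median of -0.16. The test gave an adjusted p of 0.00123, and adjusted p = 0.979 with an estimated correlation. Of ribosome biogenesis factors, 7 of 33 were lower and none higher (also 7 adjusted over the list alone, 13 with the block), with a median of -0.19, among them the nucleolar helicase DDX21 (-0.44 ± 0.09). Camera gave an adjusted p of 0.00374, and adjusted p = 0.979 with an estimated correlation. These 4 lists were the only ones of 36 called for EloB KD. Under quantile scaling the calls of the ribosomal protein (adjusted p 0.911), ribosome biogenesis (0.231) and HOX lists (0.056) ended, over ranges of 0.000248 to 0.979, 0.000248 to 0.979 and 5.53e-05 to 0.979. That of ribosome biogenesis also ended without Control KD replicate 3 (0.0581) or EloB KD replicate 1 (0.0508).

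Genes of apoptosis were of interest because the series concerns cell death on inhibition of Elongin BC. Among pro-apoptotic genes in EloB KD, 2 of 25 were higher and 3 lower (6 and 7 with the block), with a median of 0.07, a mean of -0.001 and an adjusted p of 0.975. TNFRSF10A, the death receptor DR4 (-0.61 ± 0.09), and BCL2L11, which encodes BIM (-0.51 ± 0.11), fell. Among 14 anti-apoptotic genes 4 were higher and none lower (5 and 3 with the block), including BCL2L1 (0.73 ± 0.12), which encodes BCL-XL (chromosome 20, 31664452 to 31723989). This list had a median of -0.09 and a mean of 0.16 and was not called (adjusted p 0.709). HIF target genes gave 2 higher and 4 lower members of 34 (7 and 9 with the block), with a median of -0.07 and an adjusted p of 0.764. Genes of the Elongin and cullin ligase core (2 of 14 lower, adjusted p 0.394) and of BC-box substrate receptors (3 higher and 6 lower of 38, adjusted p 0.602) were not called either. Mitosis genes had no called member (median -0.12, adjusted p 0.394), and here EloB KD replicate 1 stood apart, with a mitosis score of -0.762 against 0.191 and 0.125 in replicates 2 and 3. Mitosis genes were called as lower without EloB KD replicate 2 (0.0162) or 3 (0.0494), and over all its alternatives the adjusted p was 0.0162 to 0.979.

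**Figure D2:**
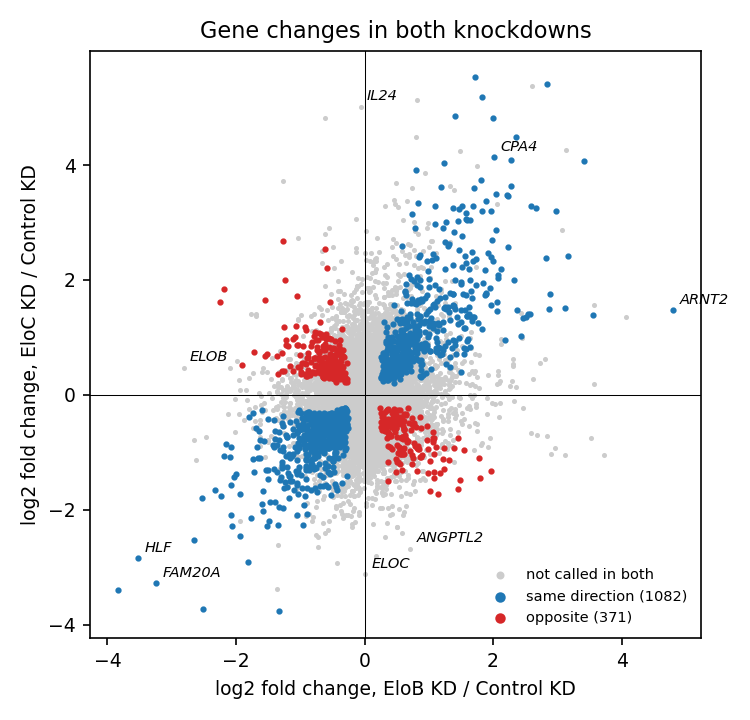
Log2 fold changes against Control KD of the genes tested in the knockdown experiment, EloB KD on the horizontal and EloC KD on the vertical axis, with genes called in both knockdowns coloured by direction. ELOB and ELOC lie on separate axes, and 1082 genes were called in the same direction.

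EloC KD was compared with Control KD to ask the same of Elongin C. The targeted gene ELOC had 491.8, 497.4 and 557.9 normalised counts in EloC KD against 4797, 4097 and 4547 in Control KD, and fell by 3.12 ± 0.10 on the log2 scale (8.67-fold, adjusted p 1.41e-07). ELOA fell by 0.73 ± 0.10 (3949 ± 296 against 6557 ± 357 normalised counts, adjusted p 0.000332). ELOB had a log2 fold change of 0.47 ± 0.20 (5255 ± 600 against 3898 ± 1180, adjusted p 0.0803), which passed with the replicate block (adjusted p 0.035) and without Control KD replicate 3 (log2 0.67, adjusted p 0.0187). Over all alternatives its adjusted p was 0.0187 to 0.26.

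The carboxypeptidase gene CPA4 rose 17.7-fold in EloC KD (7417 ± 1590 against 430.2 ± 157 normalised counts). The cytokine IL24 rose 32.4-fold (988.2 ± 486 against 27.68 ± 6.01), the stromelysin MMP3 28.9-fold, CNTN5 42.5-fold and ANKRD1, a target of YAP, 41.5-fold. The myosin light chain gene MYL10 fell 13.6-fold, FAM20A 9.69-fold and HLF 7.17-fold. In limma 5844 of 13764 genes were called, 2926 higher and 2918 lower, and 1435 changed at least 2-fold. The counts of edgeR (5878), DESeq2 (6275) and the block (7841, among them all 5844) were higher, and 5788 of the 5844 were called in the authors' table, none in the opposite direction.

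NF-kB targets and inflammatory cytokines rose in EloC KD, with 16 of 24 members higher and 3 lower (the same adjusted over the list alone) and a median log2 fold change of 1.29. TNFAIP3, the A20 deubiquitinase that is induced by and restrains NF-kB, rose 9.76-fold (1861 ± 344 against 188 ± 13.6; chromosome 6, 137867188 to 137883312), IL6 12.1-fold and NFKBIA, the inhibitor IκBα, 2.33-fold, and the chemokine CCL20 went from 1.104 ± 1.23 to 67.22 ± 9.97 normalised counts. The list was called by camera (adjusted p 1.35e-05, and adjusted p = 0.331 with an estimated correlation). Lysosome and autophagy genes rose too, with 21 of 29 members higher and none lower (22 adjusted over the list alone) and a median of 0.68. For this list the adjusted p was 6.01e-07, and adjusted p = 0.457 with an estimated correlation. They include the autophagy receptor SQSTM1 (log2 1.52 ± 0.16), the protective protein cathepsin A, CTSA (1.17 ± 0.14), and GPNMB (2.12 ± 0.27). Of the NRF2 targets, 14 of 22 were higher and 2 lower (15 and 2 adjusted over the list alone), with a median of 0.46. The adjusted p was 0.000276, and adjusted p = 0.457 with an estimated correlation. They were led by the heme oxygenase HMOX1 (2.03 ± 0.11) and the ketoreductase AKR1C1 (2.19 ± 0.25), which has close paralogs whose reads the counting could mix with its own. Targets of YAP and TAZ rose in 14 of 21 cases and fell in 2 (the same adjusted over the list alone), with a median of 0.69 and the matricellular protein gene CCN1 at 2.28 ± 0.28. Camera gave an adjusted p of 0.000135, and adjusted p = 0.457 with an estimated correlation. Immediate early genes gave 16 of 27 higher and 6 lower (17 and 6 adjusted over the list alone), with a median of 0.61. For this list the adjusted p was 0.00503, and adjusted p = 0.457 with an estimated correlation, with ATF3 (2.36 ± 0.17), DUSP5 (1.79 ± 0.11) and EGR2 (1.61 ± 0.14) higher and the feedback inhibitor SPRY4 (-0.95 ± 0.10) lower. TGF-beta and mesenchymal genes gave 11 of 28 higher and 2 lower (the same adjusted over the list alone), with a median of 0.35 and an adjusted p of 0.00648 (adjusted p = 0.584 with an estimated correlation), among them TGFB2 (2.06 ± 0.25), N-cadherin CDH2 (1.62 ± 0.15) and ITGA5 (1.51 ± 0.14). Without EloC KD replicate 2 the median of this list was 0.189 (adjusted p 0.0319), over a range of 0.000844 to 0.584.

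Ribosomal protein genes fell in EloC KD, with 28 of 62 members lower and none higher (31 lower and 1 higher adjusted over the list alone) and a median of -0.25 (adjusted p 1.35e-05, and adjusted p = 0.512 with an estimated correlation). RPL4 was lower by far more than the rest (log2 -2.24 ± 0.12, 4.73-fold; a direct effect of the hairpin, whose sequence was not analysed here, was not tested), followed by RPL3 (-1.02 ± 0.11) and RPL27 (-0.80 ± 0.10). Nuclear genes of oxidative phosphorylation gave 18 of 34 lower and 2 higher (20 and 2 adjusted over the list alone), with a median of -0.27. The adjusted p was 0.000209, and adjusted p = 0.5 with an estimated correlation, with the ATP synthase subunit ATP5F1B at -0.91 ± 0.12 and the complex I subunit NDUFV2 at -0.71 ± 0.10, but the complex IV subunit COX7C at 0.81 ± 0.09. Genes of cholesterol and fatty acid synthesis gave 18 of 28 lower and none higher (the same adjusted over the list alone), with a median of -0.51. Camera gave an adjusted p of 0.000222, and adjusted p = 0.457 with an estimated correlation. INSIG1 was at -1.63 ± 0.21, FADS1 at -1.27 ± 0.17 and SREBF2, the master regulator of sterol synthesis, at -0.91 ± 0.09. HOX genes were called as higher, with 11 of 29 higher and 3 lower (12 and 3 adjusted over the list alone) and a median of 0.55. For this list the adjusted p was 0.0226, and adjusted p = 0.563 with an estimated correlation. HOXB13 (-1.50 ± 0.18) was lower and HOXC6 (1.29 ± 0.18) higher.

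Pro-apoptotic genes were called as higher in EloC KD, with 8 of 25 members higher and none lower (the same adjusted over the list alone) and a median of 0.15. The adjusted p was 0.039, and adjusted p = 0.457 with an estimated correlation. The BH3-only gene BMF rose 5.55-fold (2079 ± 668 against 371.1 ± 109), the death receptor FAS 2.64-fold and PMAIP1, which encodes NOXA, 1.76-fold. The call of the list ended without Control KD replicate 2 (adjusted p 0.0537), its median was 0.227 without Control KD replicate 3, and over all its alternatives the adjusted p was 0.024 to 0.457. Anti-apoptotic genes moved both ways (3 higher and 4 lower, median 0.004, adjusted p 0.986), with BIRC3 (log2 3.28 ± 0.39) and BCL2L1 (0.88 ± 0.12) higher and FAIM (-1.31 ± 0.18) and the mitotic survivin gene BIRC5 (-1.42 ± 0.28) lower. HIF targets were not called (6 higher and 14 lower of 34, median -0.13, adjusted p 0.212), although the MYC antagonist MXI1 (-1.39 ± 0.18), NDRG1 (-1.20 ± 0.19) and PDK1 (-0.56 ± 0.09) fell. Without Control KD replicate 3 the HIF list was called as lower (0.0398), over a range of 0.0398 to 0.847. Genes of the Elongin and cullin ligase core (1 higher and 3 lower, 4 and 3 with the block, adjusted p 0.445), BC-box substrate receptors (6 and 9, median 0.005, mean -0.011, adjusted p 0.726) and mitosis genes (2 lower and 6 with the block, median -0.23, adjusted p 0.165) were not called. Mitosis genes were called as lower without Control KD replicate 1 (0.0399) or EloC KD replicate 3 (0.0486), over a range of 0.0399 to 0.847. With the block 13 lists were called in place of 11. The additions were genes of G1/S and DNA replication (1 higher and 7 lower of 38, 1 and 13 with the block; median -0.23, adjusted p 0.0471, and 0.0739 without the block) and histone genes (6 of 17 lower; median -0.29, adjusted p 0.0441, and 0.0615 without it). Either list also passed without Control KD replicate 1 (0.00442 and 0.04) and without 1 other library.

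The knockdowns were then compared with each other, to ask whether depleting either subunit of the same heterodimer has the same result. ELOB was lower in EloB KD (log2 -3.29 ± 0.20) and ELOC higher (3.12 ± 0.10), and ELOA was higher in EloB KD than in EloC KD (0.51 ± 0.10, adjusted p 0.00237). CHRNA1 (27.5-fold) and MYOD1 (15.3-fold) were higher in EloB KD. SUN3 (43.5-fold), IL24 (33.8-fold) and the tight junction gene CLDN1 (13.7-fold) were higher in EloC KD. Limma called 6343 of 13764 genes between the knockdowns, 3063 higher in EloB KD and 3280 lower, more than either knockdown gave against Control KD.

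By list, NF-kB targets had the largest median difference, at -1.41. They were lower in EloB KD in 16 of 24 cases and higher in 1 (17 and 1 adjusted over the list alone), with TNFAIP3 at -2.20 ± 0.14 and IL6 at -2.86 ± 0.27 (adjusted p 0.000339, and adjusted p = 0.492 with an estimated correlation). Lysosome genes were lower in EloB KD in 19 of 29 cases and higher in 1 (20 and 1 adjusted over the list alone), with a median of -0.64 and SQSTM1 at -1.40 ± 0.16 (adjusted p 0.000752, and adjusted p = 0.664 with an estimated correlation). NRF2 targets were lower in 14 of 22 cases and higher in none (15 and none adjusted over the list alone), with a median of -0.58 and HMOX1 at -1.94 ± 0.11 (adjusted p 0.000876, and adjusted p = 0.492 with an estimated correlation). YAP and TAZ targets were lower in 17 of 21 cases and higher in 3 (the same adjusted over the list alone), with a median of -0.71 and CCN1 at -1.93 ± 0.28 (adjusted p 0.00219, and adjusted p = 0.589 with an estimated correlation). Immediate early genes were lower in 15 of 27 cases and higher in 5 (16 and 5 adjusted over the list alone), with a median of -0.68 and the phosphatase DUSP5 at -1.84 ± 0.11 (adjusted p 0.0143, and adjusted p = 0.492 with an estimated correlation).

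Ribosome biogenesis factors were lower in EloB KD than in EloC KD in 18 of 33 cases and higher in none (19 and none adjusted over the list alone), with a median of -0.37 and RRP12 at -0.81 ± 0.12 (adjusted p 0.00219, and adjusted p = 0.712 with an estimated correlation). STAT3 targets were lower in 7 of 14 cases and higher in 1 (9 and 2 adjusted over the list alone), with a median of -0.51 and the feedback inhibitor SOCS3 at -1.31 ± 0.15 (adjusted p 0.0208, and adjusted p = 0.492 with an estimated correlation). TGF-beta and mesenchymal genes were lower in 14 of 28 cases and higher in 4 (the same adjusted over the list alone), with a median of -0.42 (adjusted p 0.0199, and adjusted p = 0.739 with an estimated correlation). Their call ended without EloC KD replicate 2 (0.0684), and over all alternatives their adjusted p was 0.00757 to 0.739. Oxidative phosphorylation genes were higher in EloB KD in 10 of 34 cases and lower in 1 (the same adjusted over the list alone, 17 and 1 with the block), with a median of 0.19 (adjusted p 0.0199, and adjusted p = 0.755 with an estimated correlation). Their call ended without EloB KD replicate 3 (0.0765) or EloC KD replicate 1 (0.0501), and over all alternatives their adjusted p was 0.000822 to 0.755. The block added histone genes (adjusted p 0.0443, and 0.0591 without it) and proteasome genes (0.0402, and 0.059 without it) to these 9 lists. Either list also passed without EloB KD replicate 2 (0.0205 and 0.018). Mitosis genes, not called (median 0.03, adjusted p 0.66), passed as higher in EloB KD without EloB KD replicate 1 (0.000521), over a range of 0.000521 to 0.99.

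Between the knockdowns 1082 genes were called in the same direction and 371 in opposite directions, against 599 and 599.2 for independent lists. With the block these counts were 2203 and 938, against 1423 each. Across genes, which are not independent replicates, the fold changes of EloB KD and EloC KD correlated with r = 0.333 (rho 0.262). Unchanged groups simulated against the same Control KD libraries gave r = 0.5, and a covariance of 0.0222 against the 0.117 observed, a difference of 0.0952. These simulations leave out the pairing by replicate number, and from the spread with the block a shared control gives a covariance of 0.0125, a difference of 0.105. Part of any excess may come from the shared controls, which are too few to split.

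The WT peptide was compared with the scrambled peptide to ask what a peptide that carries the BC-box does to PC3 cells. The genes of the Elongin complex had log2 fold changes near 0 (ELOB 0.03 ± 0.05, ELOC 0.07 ± 0.05 and ELOA -0.06 ± 0.06; adjusted p 0.642 to 0.862). Mitosis genes rose together. CCNB1, the cyclin that drives entry into mitosis, rose 1.83-fold (5816 ± 151 against 3198 ± 342 normalised counts; log2 0.87 ± 0.07, adjusted p 0.0015; chromosome 5, 69167010 to 69178245). The mitotic kinase PLK1 rose 1.67-fold (4180 ± 84.3 against 2511 ± 229), the kinesin KIF20A 1.71-fold, the centromere gene CENPE 1.76-fold and the survivin gene BIRC5 1.40-fold. Of the 32 mitosis genes measured, 27 were higher and none lower (31 adjusted over the list alone; 32 with the block), with a median log2 fold change of 0.49. The list was called with an adjusted p of 2.5e-53, an adjusted p = 0.113 with an estimated correlation and an adjusted p of 0.00136 by fry.

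The gene with the largest rise was CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, at 3.25-fold (117.1 ± 18 against 35.65 ± 7.94; adjusted p 0.00365; chromosome 15, 74719542 to 74725610). Among the genes that fell were the chemokine CXCL3 (2.74-fold, adjusted p 0.0251; chromosome 4, 74036589 to 74038807), the adhesion molecule L1CAM (2.13-fold), MMP10 (1.99-fold), the calcium binder S100P (1.96-fold; 1072 ± 114 against 2103 ± 210), the sterol exporter ABCG1 (1.93-fold) and the integrin ITGB4 (1.88-fold). BCL2L1 fell 1.25-fold (7237 ± 221 against 9038 ± 403, adjusted p 0.0161). Limma called 188 of 13105 genes, 110 higher and 78 lower, 7 of them at least 2-fold; edgeR called 200 and DESeq2 531. With the block 2122 genes were called, 1043 higher and 1079 lower, among them the 188. All 188 were called in the authors' table, none in the opposite direction, but 0 of its 506 calls reached 2-fold. The limma count was 67 and 66 without WT peptide replicates 1 and 3, and 95 and 98 without scrambled peptide replicates 1 and 2. The call of CXCL3 ended without any of WT peptide replicates 1 (adjusted p 0.0606), 2 (0.0745) and 3 (0.133) and scrambled peptide replicates 1 (0.0793) and 3 (0.072). The call of ITGB4 ended without WT peptide replicates 1 (0.12), 2 (0.0707) or 3 (0.163) or scrambled peptide replicates 1 (0.135) or 2 (0.115). That of ABCG1 ended without WT peptide replicates 1 (0.0854), 2 (0.0596) or 3 (0.0812) or scrambled peptide replicates 1 (0.088) or 3 (0.0552). BCL2L1 lost its call without WT peptide replicates 1 (0.0724) or 3 (0.0711) or scrambled peptide replicate 1 (0.0557), L1CAM without WT peptide replicates 1 (0.0713) or 3 (0.0652) or scrambled peptide replicate 2 (0.0522), and MMP10 without WT peptide replicate 1 (0.0724). Over all alternatives the adjusted p of each of these 6 genes was below 1e-05 at its lowest, and at its highest 0.133 for CXCL3, 0.163 for ITGB4, 0.088 for ABCG1, 0.0724 for BCL2L1 and MMP10 and 0.0713 for L1CAM.

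**Figure D3:**
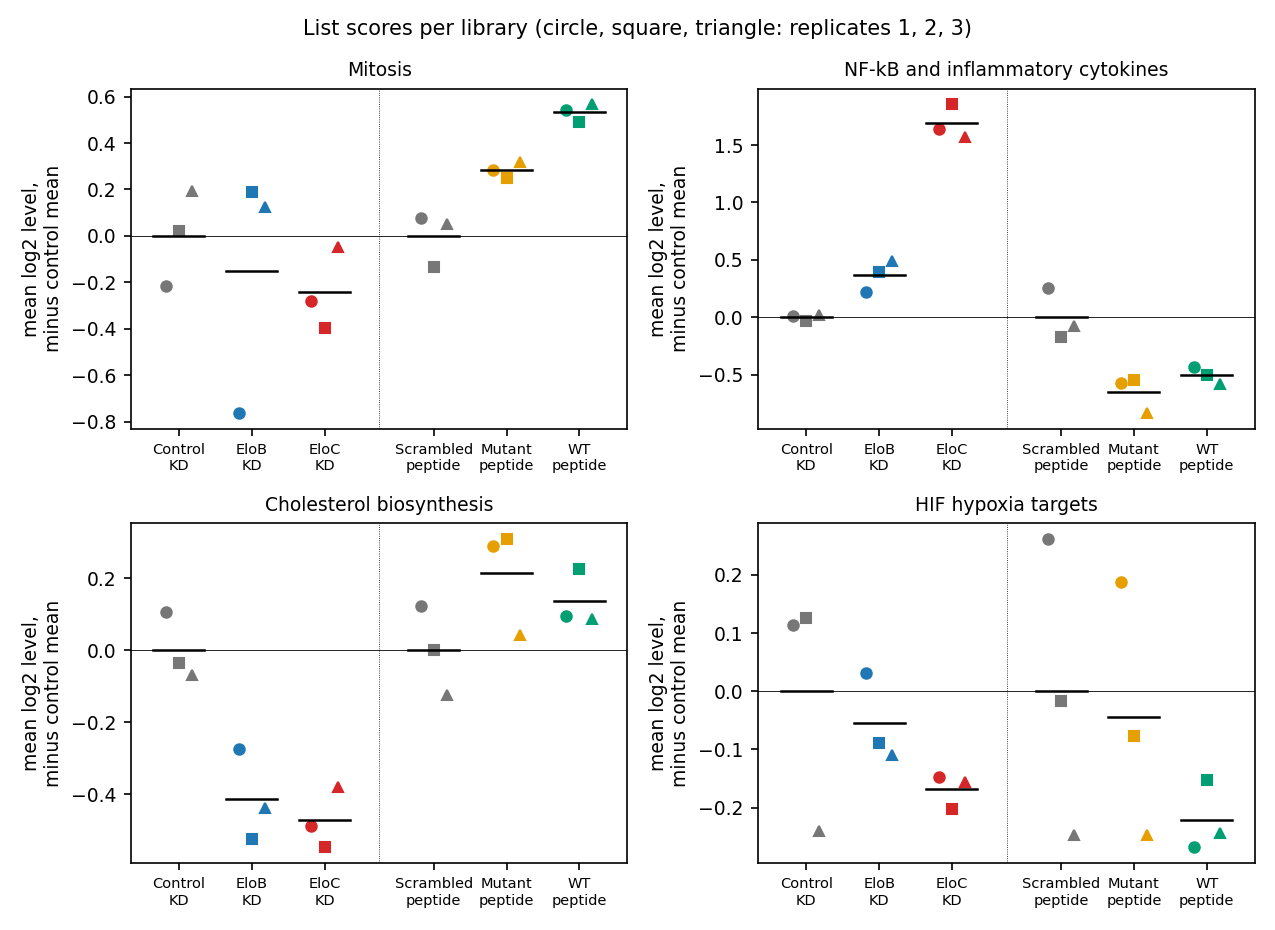
List scores of mitosis, NF-kB, HIF and cholesterol genes per library, as mean log2 difference from the control mean (Control KD or scrambled peptide), with replicates marked. The mitosis score is 0.49 to 0.566 with the WT peptide, 0.25 to 0.319 with the mutant peptide and -0.133 to 0.079 with the scrambled peptide.

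NF-kB targets and inflammatory cytokines fell with the WT peptide as a list, with 2 of 22 members called lower and none higher (10 lower adjusted over the list alone, 13 lower and 1 higher with the block) and a median of -0.44. Camera gave an adjusted p of 2.51e-09, and adjusted p = 0.253 with an estimated correlation. The cytokine gene IL1B was lower 1.58-fold (3143 ± 341 against 4944 ± 319, adjusted p 0.00498) beside CXCL3, while CXCL2 (log2 -1.32 ± 0.28, adjusted p 0.0576) and CXCL8 (-1.04 ± 0.22, adjusted p 0.0534) did not pass. Without scrambled peptide replicate 2 CXCL2 (0.01) and CXCL8 (0.00423) passed, as they did with the block (0.000175 and 2.57e-05), in edgeR and in DESeq2. HIF targets were lower as a list, since 32 of 34 members lay below 0, although none was called (4 lower adjusted over the list alone, 18 lower with the block). The median was -0.21 and the adjusted p 4.18e-07, and adjusted p = 0.473 with an estimated correlation. ANKZF1 had a log2 fold change of -0.45 ± 0.10 (adjusted p 0.0594, and 0.0436 without scrambled peptide replicate 3), PDK1, a kinase that curbs pyruvate oxidation, -0.35 ± 0.09 and the mitophagy receptor BNIP3L -0.35 ± 0.09. The HIF score of the scrambled peptide libraries ranged from -0.246 in replicate 3 to 0.262 in replicate 1, and that of the WT peptide libraries from -0.268 to -0.153. Without scrambled peptide replicate 1 the median of HIF targets was -0.104 (adjusted p 0.00382), and without scrambled peptide replicate 3 it was -0.322 (3.33e-12), over a range of 3.33e-12 to 0.473. Immediate early genes were lower as a list, with 1 of 28 called lower and none higher (4 lower adjusted over the list alone, 12 with the block) and a median of -0.17 (adjusted p 0.000175, and adjusted p = 0.253 with an estimated correlation). STAT3 targets were lower too, with 1 of 13 called lower and none higher (3 lower adjusted over the list alone, 5 with the block) and a median of -0.20 (adjusted p 0.000393, and adjusted p = 0.113 with an estimated correlation). The median of STAT3 targets was -0.101 without WT peptide replicate 1 and -0.113 without WT peptide replicate 3.

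Several lists of housekeeping genes were called as higher with the WT peptide by small amounts, although no member of them passed singly. Of 62 ribosomal protein genes, 58 lay above 0, with a median of 0.06 (none called adjusted over the list alone, 13 higher with the block). For this list the adjusted p was 1.88e-06, and adjusted p = 0.253 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.08 (none called adjusted over the list alone, 10 higher with the block) and an adjusted p of 3.75e-05 (adjusted p = 0.253 with an estimated correlation). Cholesterol synthesis genes had a median of 0.14 (none called adjusted over the list alone, 10 higher with the block) and an adjusted p of 3.78e-05 (adjusted p = 0.508 with an estimated correlation). Their median was 0.0841 without WT peptide replicate 2 and 0.0772 without scrambled peptide replicate 3. Proteasome genes had a median of 0.07 (none called adjusted over the list alone, 7 higher with the block) and an adjusted p of 0.000175 (adjusted p = 0.417 with an estimated correlation). Ribosome biogenesis factors had a median of 0.06 (1 higher adjusted over the list alone, 4 with the block) and an adjusted p of 0.000387 (adjusted p = 0.404 with an estimated correlation). Heat shock genes had a median of 0.11 (0.0574 without scrambled peptide replicate 2; 3 higher adjusted over the list alone, 9 with the block) and an adjusted p of 0.000527 (adjusted p = 0.404 with an estimated correlation).

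A further 4 lists were called for the WT peptide with an adjusted p above 0.02, and each lost its call without some single library. G1/S and DNA replication genes (1 of 38 lower, 3 lower adjusted over the list alone, 7 lower and 3 higher with the block) had a median of -0.06 and an adjusted p of 0.0274, or adjusted p = 0.578 with an estimated correlation. This call ended with the block (0.0955) and without WT peptide replicate 2 (0.291), without scrambled peptide replicate 3 (0.262) or without replicate 2 of every group (0.162), and over all alternatives the adjusted p was 0.000732 to 0.578. Interferon genes (none of 36 called, 12 lower with the block) had a median of -0.17 and an adjusted p of 0.03, or adjusted p = 0.766 with an estimated correlation. Their call ended without scrambled peptide replicate 2 (0.089), and also without WT peptide replicate 3 (median 0.016, adjusted p 0.947) or scrambled peptide replicate 1 (median 0.015, adjusted p 0.812), where the median changed sign, over a range of 1.02e-07 to 0.947. Unfolded protein response genes (none of 21 called, 3 higher adjusted over the list alone, 7 with the block) had a median of 0.04 and an adjusted p of 0.04, or adjusted p = 0.405 with an estimated correlation. That call ended without WT peptide replicates 1 (0.0951) or 2 (0.076) or scrambled peptide replicates 1 (0.0855) or 2 (0.0655) and under quantile scaling (0.197) or a mean count of at least 50 (0.0522), over a range of 0.0153 to 0.405. Epithelial genes (none of 21 called, 2 lower adjusted over the list alone, 5 with the block) had a median of -0.10 and an adjusted p of 0.0469, or adjusted p = 0.253 with an estimated correlation. Here the call ended without WT peptide replicates 1 (0.0847), 2 (0.0543) or 3 (0.0737) or scrambled peptide replicates 1 (0.0944) or 2 (0.0655) and under quantile scaling (0.0897), over a range of 0.0139 to 0.253. Among these 4 lists the median was -0.0867 for G1/S genes without WT peptide replicate 1, and without scrambled peptide replicate 3 it was 0.0773 for unfolded protein response, -0.375 for interferon and -0.154 for epithelial genes. Of all lists 15 were called for the WT peptide, and 15 with the block, which put mitochondrially encoded mRNAs (median 0.08, adjusted p 0.00102, and 0.26 without the block) in place of the G1/S list. These mRNAs also passed without WT peptide replicate 1 (0.00482) or scrambled peptide replicate 2 (0.000558). Pro-apoptotic genes were not called (no member of 25, 2 higher and 1 lower with the block, median 0.003, mean -0.076, adjusted p 0.776).

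The mutant peptide was compared with the scrambled peptide to ask what remains of the response when the BC-box is altered. ELOB (log2 0.02 ± 0.05), ELOC (0.05 ± 0.05) and ELOA (-0.05 ± 0.06) were near 0. No gene passed in limma, where 1142 genes had an unadjusted p under 0.05 and 655 are expected by chance. EdgeR also called 0 genes, DESeq2 165, and limma with the block 1088 (487 higher and 601 lower). With the block KIF20A (log2 0.40, adjusted p 0.000127, and 0.0912 without the block), CENPF (0.41, 0.00027 and 0.0739) and MKI67 (0.34, 0.00027 and 0.0739), all genes of dividing cells, were higher. CXCL3 (-1.44, 3.28e-05 and 0.114), the NF-kB subunit RELB (-0.89, 0.000623 and 0.112), TNFAIP3 (-0.86, 0.000371 and 0.12) and IL1B (-0.45, 8.42e-05 and 0.12) were lower with the block. Over the alternatives the adjusted p of these 7 genes reached at most 0.268 to 0.297.

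By list, mitosis genes were higher with the mutant peptide. All 32 lay above 0 and none was called singly (28 higher adjusted over the list alone, 31 with the block), and the median was 0.27 (adjusted p 9.69e-38, and adjusted p = 0.0914 with an estimated correlation; 0.0233 by fry). NF-kB targets were lower, with none called singly (15 lower adjusted over the list alone, 16 lower and 1 higher with the block) and a median of -0.73 (adjusted p 6.99e-16, and adjusted p = 0.0914 with an estimated correlation). Cholesterol synthesis genes were higher, with none called singly (9 higher adjusted over the list alone, 16 with the block) and a median of 0.21 (adjusted p 3.78e-14, and adjusted p = 0.209 with an estimated correlation). Ribosomal protein genes had a median of 0.07 (none called adjusted over the list alone, 13 higher with the block) and an adjusted p of 6.49e-10 (adjusted p = 0.13 with an estimated correlation). Oxidative phosphorylation genes also had a median of 0.07 (none called adjusted over the list alone, 9 higher with the block), with an adjusted p of 5.44e-07 (adjusted p = 0.144 with an estimated correlation). Immediate early genes were lower, with none called singly (4 lower adjusted over the list alone, 13 with the block) and a median of -0.18 (adjusted p 7.4e-09, and adjusted p = 0.0914 with an estimated correlation). STAT3 targets were lower as well, with none called singly (2 lower adjusted over the list alone, 4 with the block) and a median of -0.15 (adjusted p 3.14e-06, and adjusted p = 0.0656 with an estimated correlation). Their median was -0.23 without mutant peptide replicate 2 and -0.234 without scrambled peptide replicate 1.

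A further 5 lists were called for the mutant peptide with an adjusted p above 0.03, and each lost its call without some single library. TGF-beta and mesenchymal genes (1 lower adjusted over the list alone, 4 lower and 1 higher with the block) had a median of -0.13 and an adjusted p of 0.0361, or adjusted p = 0.192 with an estimated correlation. The call ended without mutant peptide replicate 2 (0.0746) or scrambled peptide replicate 1 (0.22), under quantile scaling (0.0633) and at a mean count of at least 50 (0.0594), over a range of 0.00715 to 0.22. Epithelial genes (none called adjusted over the list alone, 4 lower with the block) had a median of -0.07 and an adjusted p of 0.0361, or adjusted p = 0.157 with an estimated correlation. Their call ended without mutant peptide replicate 3 (0.17) or scrambled peptide replicates 1 (0.112) or 2 (0.0573), over a range of 0.0062 to 0.17. YAP and TAZ targets (none called adjusted over the list alone, 6 lower with the block) had a median of -0.07 and an adjusted p of 0.0361, or adjusted p = 0.267 with an estimated correlation. That call ended without mutant peptide replicate 2 (0.0746) or scrambled peptide replicates 1 (0.0878) or 3 (0.0565), over a range of 0.0019 to 0.267. Lysosome genes (3 lower adjusted over the list alone, 6 with the block) had a median of -0.04 and an adjusted p of 0.0361, or adjusted p = 0.15 with an estimated correlation. Here the call ended without mutant peptide replicate 2 (0.133) or scrambled peptide replicates 1 (0.0878) or 3 (0.0814), over a range of 0.0076 to 0.15. Proteasome genes (none called adjusted over the list alone or with the block) had a median of 0.03 and an adjusted p of 0.04, or adjusted p = 0.725 with an estimated correlation. This one ended without mutant peptide replicate 3 (0.905) or scrambled peptide replicates 1 (0.132) or 2 (0.288) and under quantile scaling (0.178), over a range of 0.00231 to 0.905. Without mutant peptide replicates 1, 2 and 3 the median of proteasome genes was 0.0514, 0.0581 and 0.006, without scrambled peptide replicates 2 and 3 0.0129 and 0.0644. Epithelial genes had -0.14 and -0.0435 without mutant peptide replicates 2 and 3, and -0.0317 and -0.121 without scrambled peptide replicates 2 and 3. TGF-beta genes had -0.0705 without mutant peptide replicate 3 and -0.0611 and -0.0847 without scrambled peptide replicates 1 and 3, and lysosome genes -0.0655 without scrambled peptide replicate 2. With the block 17 lists were called in place of 12. The additions were p53 targets (adjusted p 0.0474, and 0.0613 without the block), ATF4 targets (0.00925 and 0.0544), G1/S genes (0.0349 and 0.208), interferon genes (0.0062 and 0.208) and mitochondrially encoded mRNAs (0.00642 and 0.332), and each of these also passed without some single library. HIF targets were not called (median -0.06, adjusted p 0.167), but were lower without mutant peptide replicate 1 (1.49e-05) or scrambled peptide replicate 3 (1.74e-05), over a range of 1.49e-05 to 0.809.

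The WT peptide was compared directly with the mutant peptide, the related molecule with an altered BC-box, given at the same dose and for the same time. No gene passed in limma or edgeR, and 898 genes had an unadjusted p under 0.05 in limma with 655 expected by chance. DESeq2 called 54 genes, and limma with the block called 536, 315 higher and 221 lower with the WT peptide. With the block, CCNB1 was higher with the WT peptide by 0.49 on the log2 scale (95% interval 0.37 to 0.61), PLK1 by 0.43 (0.34 to 0.53), KIF20A by 0.37 (0.28 to 0.47) and CYP1A1 by 1.38 (1.0 to 1.75). BCL2L1 differed by -0.12 (-0.19 to -0.06) and IL1B by -0.21 (-0.31 to -0.11). HMOX1 was higher with the WT peptide (1329 ± 200 against 775.5 ± 57.4 normalised counts; adjusted p 0.000314 with the block and 0.39 without it, over a range of 0.000314 to 1). The peptides were not found to differ for CXCL3 (-0.01, interval -0.29 to 0.27), CXCL8 (0.09, -0.16 to 0.33), TNFAIP3 (0.17, -0.06 to 0.41), ELOB (0.02, -0.07 to 0.11) or ELOC (0.01, -0.06 to 0.09), and for ELOA the log2 fold change was -0.01 (adjusted p 0.998).

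By list, mitosis genes were higher with the WT than with the mutant peptide. All 32 lay above 0 and none was called singly (28 higher adjusted over the list alone, 25 with the block), with a median of 0.23 (adjusted p 8.77e-34, and adjusted p = 0.4 with an estimated correlation; 0.0982 by fry). Fry called 0 of 35 lists between the peptides, where camera called 9. G1/S and DNA replication genes were lower, with 32 of 38 below 0 and none called (none adjusted over the list alone, 5 lower with the block), and with a median of -0.07. The adjusted p was 4.66e-06, and adjusted p = 0.817 with an estimated correlation, with the replicative helicase subunit MCM6 at -0.22 ± 0.05. The median of G1/S genes was -0.109 without WT peptide replicate 1, and -0.121 and -0.0309 without mutant peptide replicates 2 and 3. HIF targets were lower, with 31 of 34 below 0 and none called (none adjusted over the list alone, 7 lower with the block), and with a median of -0.18. Camera gave an adjusted p of 1.24e-06, and adjusted p = 0.817 with an estimated correlation. This call ended without mutant peptide replicate 1 (median -0.06, adjusted p 0.0804), over a range of 4.64e-11 to 0.817.

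A further 6 lists were called between the peptides with an adjusted p above 0.002, and each lost its call without some single library. Cholesterol synthesis genes (none called adjusted over the list alone, 1 lower with the block) had a median of -0.08 and an adjusted p of 0.00267, or adjusted p = 0.827 with an estimated correlation. Their call ended without WT peptide replicate 3 (0.0643) or mutant peptide replicates 1 (0.175) or 2 (0.321), over a range of 3.51e-10 to 0.827. ATF4 targets (4 higher adjusted over the list alone, 8 with the block) had a median of 0.04 and an adjusted p of 0.00412, or adjusted p = 0.789 with an estimated correlation. That call ended without mutant peptide replicate 2 (0.125), over a range of 0.000185 to 0.789. Heat shock genes (none called adjusted over the list alone, 1 higher with the block) had a median of 0.08 and an adjusted p of 0.00579, or adjusted p = 0.817 with an estimated correlation. Here the call ended without WT peptide replicate 1 (0.119), without mutant peptide replicate 2 (0.363) or without replicate 2 of every group (0.0551), over a range of 0.000143 to 0.817. Mitochondrially encoded mRNAs (none of 13 called adjusted over the list alone, 7 higher with the block) had a median of 0.15 and an adjusted p of 0.0207, or adjusted p = 0.827 with an estimated correlation. Their call ended without WT peptide replicate 2 (0.86) or mutant peptide replicates 1 (0.428) or 3 (0.117) and under quantile scaling (0.157), over a range of 5.31e-11 to 0.86. Ribosome biogenesis factors (none called adjusted over the list alone, 3 higher with the block) had a median of 0.03 and an adjusted p of 0.0333, or adjusted p = 0.817 with an estimated correlation. That call ended without WT peptide replicate 1 (0.318) or mutant peptide replicates 1 (0.16) or 2 (0.399), under quantile scaling (0.157) and without replicate 2 of every group (0.121), over a range of 0.000829 to 0.817. Proteasome genes (none called adjusted over the list alone or with the block) had a median of 0.03 and an adjusted p of 0.0361, or adjusted p = 0.827 with an estimated correlation. This one ended without WT peptide replicates 1 (0.223) or 2 (0.0507) or mutant peptide replicates 1 (0.312) or 2 (0.648), under quantile scaling (0.115) and without replicate 2 of every group (0.377), over a range of 5.68e-05 to 0.827. Among these 6 lists the median of cholesterol synthesis genes was -0.0411, -0.0332 and -0.149 without mutant peptide replicates 1, 2 and 3, and that of ATF4 targets 0.115 without WT peptide replicate 2 and 0.0943 without mutant peptide replicate 3. Heat shock genes had 0.0484 without WT peptide replicate 1 and 0.0282 without mutant peptide replicate 2. Mitochondrially encoded mRNAs had 0.244 and 0.0202 without WT peptide replicates 1 and 2, and 0.0786 and 0.264 without mutant peptide replicates 1 and 2. Ribosome biogenesis factors had 0.013 and 0.0532 without WT peptide replicates 1 and 2, and 0.00439 and 0.0609 without mutant peptide replicates 2 and 3. Proteasome genes had 0.0428 without WT peptide replicate 2 and 0.0664 without mutant peptide replicate 3. With the block 12 lists were called in place of 9. Unfolded protein response genes (adjusted p 0.038, and 0.107 without the block), interferon genes (0.00698 and 0.285) and NRF2 targets (0.0234 and 0.0597) were added, and each also passed without some single library.

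Across genes, the fold changes of the WT and mutant peptides against the scrambled peptide correlated with r = 0.635 (rho 0.596), where unchanged groups simulated against the same scrambled peptide libraries gave 0.5 on average and 0.535 at most. Without mutant peptide replicate 2 or 3 the observed r was 0.52 and 0.529, where no simulation was run. The covariance was 0.0208 against 0.0133 in the simulations, a difference of 0.00747. From the spread with the block, which allows for pairing, a shared control gives 0.00658, a difference of 0.0142. With the block 726 genes were called in the same direction with both peptides, against 88.2 for independent lists, and 2 in opposite directions, against 87.9. Part of these excesses may come from the shared scrambled peptide libraries, which are too few to split.

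**Figure D4:**
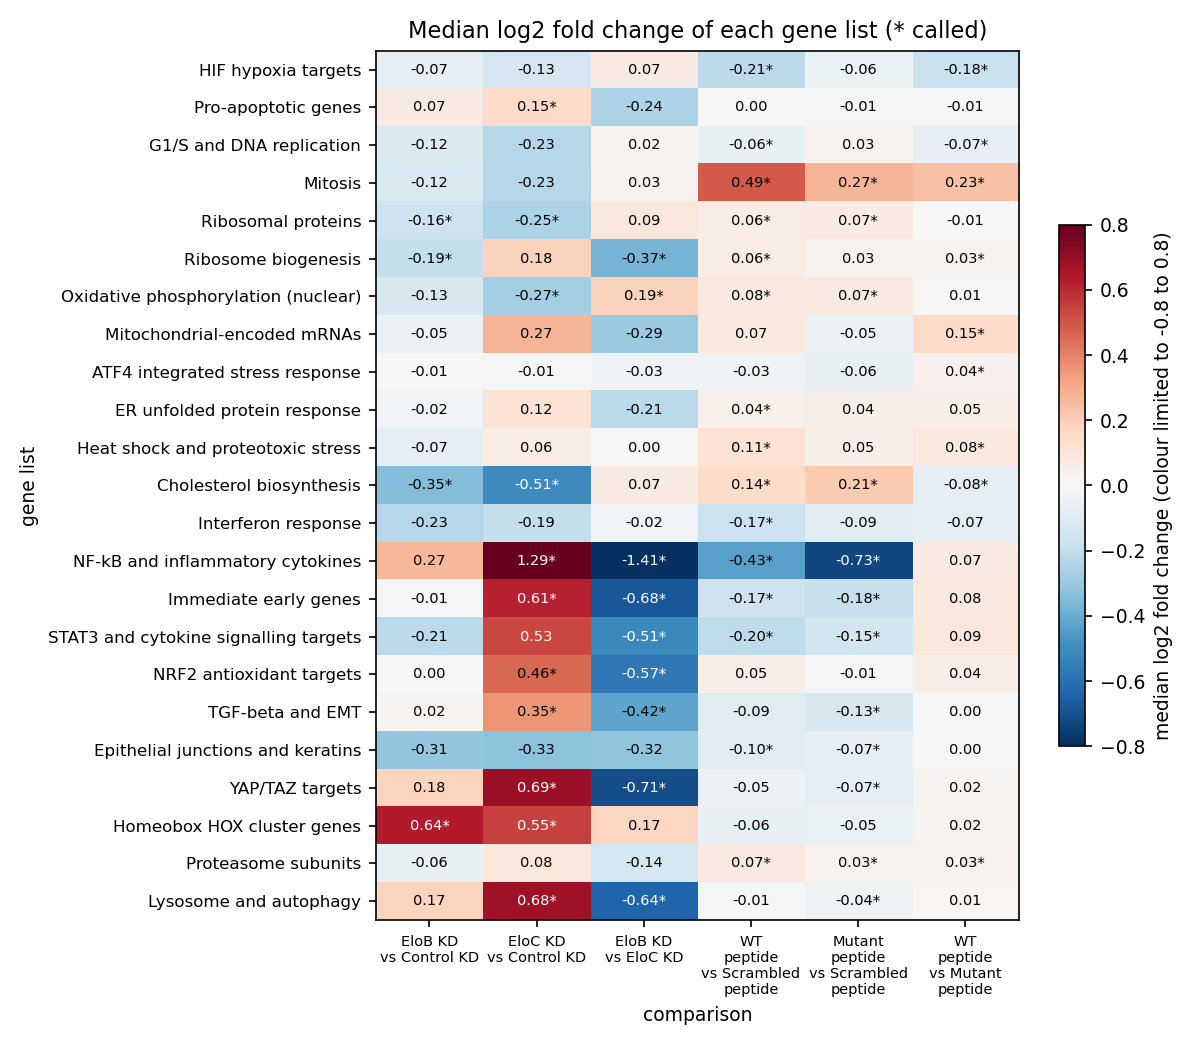
Median log2 fold change of each called gene list (vertical axis) in the comparisons with a control (horizontal axis), as colour and printed value. Ribosomal protein, oxidative phosphorylation and cholesterol synthesis lists have medians of -0.25, -0.27 and -0.51 in EloC KD and of 0.06, 0.08 and 0.14 with the WT peptide.

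The knockdowns and the WT peptide were set side by side to ask whether the peptide moves the genes that loss of its target moves. The experiments differ in serum, duration and mode of inhibition and were normalised separately, so only fold changes within each were compared. Across genes, the fold changes of the WT peptide correlated with r = -0.0797 (rho -0.078) with EloB KD and r = -0.0547 (rho 0.00611) with EloC KD, and those of the mutant peptide with r = -0.105 (rho -0.11) with EloB KD and r = -0.269 (rho -0.232) with EloC KD. The value for EloB KD was -0.0179 without EloB KD replicate 1, -0.043 without Control KD replicate 3, -0.0208 without WT peptide replicate 2 and -0.041 without scrambled peptide replicate 3. That for EloC KD was -0.0285 without Control KD replicate 3, -0.00392 without WT peptide replicate 2, and -0.107 and 0.00943 without scrambled peptide replicates 2 and 3. EloB KD and the WT peptide shared 25 genes in the same direction and 15 in opposite directions, against 18.5 and 19.5 for independent lists. EloC KD and the WT peptide shared 30 and 33 genes, against 40.2 and 40.5. With the block these counts were 400 and 459 for EloB KD, against 387 and 386, and 645 and 693 for EloC KD, against 613.8 and 613.7. For the mutant peptide, where limma without the block called no gene, they were 163 and 274 for EloB KD, against 199.3 and 196.3, and 133 and 555 for EloC KD, against 314.4 and 313.9. The count of 25 was 5 without WT peptide replicate 1, 4 without WT peptide replicate 3, 7 and 10 without scrambled peptide replicates 1 and 2, and 16 and 15 without EloB KD replicates 2 and 3. That of 30 was 6 without WT peptide replicate 1 or 3, and 10 and 13 without scrambled peptide replicates 1 and 2. A total of 8 genes were called in the same direction in all 3 comparisons (201 with the block), among them ITGB4 (log2 -1.03 in EloB KD, -1.72 in EloC KD and -0.91 with the WT peptide), FST (-2.19, -1.07 and -0.69), ABCG1 (-0.91, -0.57 and -0.95) and TMEM19 (0.39, 0.40 and 0.37). Another 12 were called in the same direction in both knockdowns and in the opposite direction with the WT peptide (248 with the block), among them CXCL3 (1.53, 2.77 and -1.45), CPA4 (2.02, 4.14 and -0.67), MMP10 (0.58, 2.60 and -0.99), the kinase gene PLK2 (1.68, 2.48 and -0.41) and BCL2L1 (0.73, 0.88 and -0.32). The count of 8 was 1 and 0 without WT peptide replicates 1 and 3, 2 and 3 without scrambled peptide replicates 1 and 2, and 5 and 4 without EloB KD replicates 2 and 3. That of 12 was 2 and 4 without WT peptide replicates 1 and 3, and 3 and 6 without scrambled peptide replicates 1 and 2. Neither count was set against independent lists, so chance stays open.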

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

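Annotated length was tested on the mitosis list, the genes that separate the knockdowns and the EloC KD part of the opposite lists. These tests were set down before their results were seen, and the others in this part were chosen only after.

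Mitosis genes were higher with the WT peptide than with the scrambled peptide, and less so with the mutant peptide. The WT and mutant peptides differed by a median of 0.232 with the preset correlation (adjusted p 8.77e-34), but camera gave adjusted p = 0.4 with an estimated correlation, fry gave an adjusted p of 0.0982, and the list lost its calls against the scrambled peptide with an estimated correlation as well (0.113 and 0.0914). The tables argue against annotated length as the whole source. With its trend removed the WT peptide median was 0.498 (0.493 before), and the WT peptide score lay above the mutant peptide score by 0.244 (SE 0.0405). The scrambled peptide libraries do not enter the difference between the WT and mutant peptides (0.248, SE 0.0407, before removal), which is part of the pattern itself. The mutant peptide lay above the scrambled peptide by 0.284, which cannot be told apart from a shift of the scrambled peptide libraries, since no group went without a peptide, and the 32 members called with the block against 27 without decide nothing on the replicate numbers, since each occurs once in every group, and no biological explanation was tested.

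EloB KD and EloC KD differed from each other in 6343 genes, although the proteins they target form a heterodimer. The tables argue against an EloB effect that is a smaller copy of the EloC effect, since 13.1% of the genes called in EloB KD were called in the opposite direction in EloC KD. They argue against scaling by a single factor per library as the whole source, since the lower of the TMM and quantile counts was 6242. They also argue against annotated length, since with the block 8159 genes were called before its trend was removed and 8185 after. What stays open is whether separate functions of the subunits or an effect of a hairpin on other mRNAs may account for the difference, and neither was tested.

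Several lists moved in opposite directions in EloC KD and with the WT peptide, in every library of both groups, and the difference between the experiments was not tested. With the annotated length trend removed, the ribosomal protein, oxidative phosphorylation and cholesterol lists kept at least 94.7% of their medians in EloC KD. With the WT peptide the lists other than cholesterol kept at least 103%. This argues against that trend as the whole source. The lengths may not be those of the expressed mRNAs, whose part stays open. With the WT peptide the cholesterol list kept 98.1%, but its score, 1.99 SE above the scrambled peptide (1.98 after), leaves open whether it moved. Serum, time and mode of inhibition cannot be told apart from the target, since 0 groups had a knockdown in low serum or a peptide in full serum. With the mutant peptide, whose BC-box is altered, the medians had the same sign as with the WT peptide (0.065 for ribosomal proteins, 0.069 for oxidative phosphorylation, 0.212 for cholesterol synthesis and -0.731 for NF-kB targets), and no biological explanation was tested.

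In the direct comparison of EloB KD with EloC KD, the tested difference in medians was -1.407 for NF-kB targets, -0.71 for YAP and TAZ targets, -0.676 for immediate early genes, -0.638 for lysosome genes, -0.575 for NRF2 targets, -0.423 for TGF-beta and mesenchymal genes, -0.37 for ribosome biogenesis factors and 0.187 for oxidative phosphorylation genes. None of these lists was called by camera with an estimated correlation (adjusted p = 0.492 to 0.755 with an estimated correlation). The call of oxidative phosphorylation genes ended without EloB KD replicate 3 (0.0765) or EloC KD replicate 1 (0.0501), and that of TGF-beta genes without EloC KD replicate 2 (0.0684). In the direct comparison of the peptides, the tested difference was -0.18 for HIF targets, -0.068 for G1/S genes, 0.079 for heat shock genes, -0.077 for cholesterol synthesis genes, 0.029 for ribosome biogenesis factors and 0.025 for proteasome genes. None of these was called with an estimated correlation (adjusted p = 0.817 to 0.827 with an estimated correlation), and fry called 0 of 35 lists in this comparison where camera called 9. The calls of these peptide lists, except G1/S, ended without mutant peptide replicate 1 (HIF 0.0804, cholesterol 0.175, ribosome biogenesis 0.16, proteasome 0.312), mutant peptide replicate 2 (cholesterol 0.321, heat shock 0.363, ribosome biogenesis 0.399, proteasome 0.648), WT peptide replicate 1 (heat shock 0.119, ribosome biogenesis 0.318, proteasome 0.223), WT peptide replicate 2 (proteasome 0.0507) or WT peptide replicate 3 (cholesterol 0.0643). Quantile scaling (ribosome biogenesis 0.157, proteasome 0.115) and leaving out replicate 2 of every group (heat shock 0.0551, ribosome biogenesis 0.121, proteasome 0.377) ended calls too.

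The lists with every EloC KD library on one side and every WT peptide library on the other were singled out for that reason, and the difference was not tested. Their medians with the WT peptide were 0.058 for ribosomal proteins (library scores -0.332 to -0.193 in EloC KD and 0.047 to 0.052 with the WT peptide), 0.081 for oxidative phosphorylation (-0.322 to -0.201 and 0.073 to 0.082) and 0.144 for cholesterol synthesis (-0.548 to -0.379 and 0.088 to 0.225). For NF-kB targets the median was -0.435 (1.573 to 1.854 and -0.583 to -0.436) and for immediate early genes -0.168 (0.483 to 0.686 and -0.232 to -0.159).

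The 6 libraries of a comparison can be split in only 10 ways, too few for a share under 0.05. In fits of those libraries alone, the real split was the 1 of 10 with the most genes for EloB KD (2418, highest other 0), for EloC KD (5647 and 0), between the knockdowns (6292 and 0) and for the WT peptide (138 and 0). For the mutant peptide limma called 0 genes in the real split and at most 0 in the others, so that all 10 gave as many, beside 1142 genes at an unadjusted p under 0.05 in the fit of 9 libraries, 0 called by edgeR and 165 by DESeq2. Between the peptides limma called 0 in the real split, so that all 10 again gave as many, and 4 in the highest other, which joins a pair of replicates of the same number. Among the 4 splits that part as many pairs the highest other was 0, beside 898 genes at an unadjusted p under 0.05, 0 called by edgeR and 54 by DESeq2.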

How the results depend on the processing

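The tests with edgeR and the block, with the length trend removed and without replicate 2 of every group were chosen only after the data were seen, and the others were planned. The counts and main values below include those that left the range of 1.5 times a count or the side of the threshold, and unless stated the cause was not tested. Among lists that were not called, 6 of 32 in EloB KD, 7 of 25 in EloC KD, 8 of 27 between the knockdowns, 4 of 20 for the WT peptide, 10 of 23 for the mutant peptide and 3 of 26 between the peptides were called under at least 1 alternative, and only some of them are named in the report. Every list called lost its call with an estimated correlation.

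With the block the genes called were 4996 in EloB KD, 2122 for the WT peptide, 1088 for the mutant peptide and 536 between the peptides. They were 5102, 2108, 1111 and 549 in edgeR with the block, and 5047, 2187, 1153 and 542 with the length trend also removed. Shared calls in the same direction were 2203 for both knockdowns, 400 for EloB KD and the WT peptide and 645 for EloC KD and the WT peptide, and ELOB in EloC KD passed at 0.4729. No list changed its call with the block beyond those named in the report, and among named genes and lists the block ended 1 call, that of the G1/S list with the WT peptide. DESeq2 called 531 genes for the WT peptide, 165 for the mutant peptide and 54 between the peptides. Without replicate 2 of every group, limma called 37 for the mutant peptide and 21 between the peptides.

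Stricter thresholds call fewer genes by construction. At a change of at least 2-fold they were 680 in EloB KD, 1435 in EloC KD, 1677 between the knockdowns and 7 for the WT peptide, and at an adjusted p under 0.01 they were 1242, 3774 (EloC KD) and 64 (WT peptide). With an estimated correlation camera called 0 lists in each of the 6 comparisons, and under quantile scaling 2 lists in EloB KD. Fry called 6 lists in EloB KD, 18 in EloC KD, 17 between the knockdowns, 6 for the WT peptide, 8 for the mutant peptide and 0 between the peptides. Scaling moved the median of all genes by at most 0.0247.

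Leaving out single libraries, the genes called were 1915 to 2373 in EloB KD, 4506 to 5413 in EloC KD, 5170 to 5626 between the knockdowns, 66 (without WT peptide replicate 3) to 180 (without scrambled peptide replicate 3) for the WT peptide and 0 to 1 (without scrambled peptide replicate 2) for the mutant peptide. The count without WT peptide replicate 1 was 67, and without scrambled peptide replicates 1 and 2 it was 95 and 98. Lists called were 4 to 7 in EloB KD (7 without Control KD replicate 2), 7 (without scrambled peptide replicate 1) to 16 (without mutant peptide replicate 1) for the mutant peptide and 4 (without mutant peptide replicate 1) to 10 (without mutant peptide replicate 3) between the peptides, with 5 without mutant peptide replicate 2. ELOB in EloC KD was 0.2124 without Control KD replicate 1 and 0.6695 without Control KD replicate 3, ELOB in EloB KD -3.08 to -2.62 and ELOC in EloC KD -3.18 to -3.07. Genes shared in the same direction were 4 (without WT peptide replicate 3) to 28 for EloB KD and the WT peptide, with 5 without WT peptide replicate 1, 7 and 10 without scrambled peptide replicates 1 and 2, and 16 and 15 without EloB KD replicates 2 and 3. For EloC KD and the WT peptide they were 6 (without WT peptide replicate 1, and also without replicate 3) to 36, with 10 and 13 without scrambled peptide replicates 1 and 2. The median of the interferon list with the WT peptide was -0.375 (without scrambled peptide replicate 3) to 0.0162 (without WT peptide replicate 3), and the list reversed without scrambled peptide replicate 1, at 0.015.

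Of the named genes called, those that kept their call under every alternative were 79 of 126 in EloB KD, 134 of 145 in EloC KD, 133 of 141 between the knockdowns and 12 of 28 for the WT peptide, and none reversed. In the self-test, which added changes to 50 genes, a log2 change of 0.5 was found in 8 of EloB KD, 9 of EloC KD and 36 of the WT peptide, and a change of 1 in 33, 39 and 41, so that small changes in the knockdowns were often missed.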

Other observations

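No tests in this part were chosen after the result was seen, but the genes were picked after their values were seen. Stress genes moved singly in EloC KD without a call of their lists. GDF15, a stress cytokine, rose 3.33-fold (3646 ± 164 against 1098 ± 109 normalised counts) and SESN2, which restrains mTORC1, 2.57-fold (1223 ± 130 against 473.5 ± 33.9). Both belong to the p53 list (9 higher and 4 lower of 23, 9 and 4 adjusted over the list alone, median 0.06, adjusted p 0.445) and to the ATF4 list (10 higher and 8 lower of 30, 11 and 9 adjusted over the list alone, median -0.01, mean 0.164, adjusted p 0.539). CCNE1, the G1/S cyclin, fell 2.46-fold in EloC KD (adjusted p 5.31e-05).

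Some genes in EloB KD and EloC KD stood apart from the rest of their lists. PSMB5, a catalytic subunit of the proteasome, fell 4.04-fold in EloB KD (4598 ± 833 against 18400 ± 519), where a direct effect of the hairpin was not tested, since its sequence was not analysed here. COX7C rose in EloB KD (2.17-fold) and in EloC KD (1.75-fold), and the immediate early gene FOS rose 3.54-fold in EloB KD. PHF19, a polycomb accessory protein, rose 1.42-fold with the WT peptide (adjusted p 0.00328).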
